A study of Mus musculus with 72 samples.

How the data were processed

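Gene expression was measured by RNA sequencing in the quadriceps muscle of 72 male C57BL/6J mice, 12 in each of 6 groups. Of these, 4 groups were young animals aged 16 weeks: fed freely (young controls), fed 60% of the calories they had eaten when fed freely (caloric restriction, CR), with the right hindleg immobilized (IR), or with both. The interventions lasted 14 days, and immobilization held the knee at 180 degrees, per the labels. The other groups were freely fed animals of 76 and 92 weeks. Per the labels, the young animals were obtained at 10 weeks and matched for body weight and lean mass at 14 weeks, while the aged animals were obtained at 58 weeks and matched at 74 weeks, so age and cohort cannot be separated. Every sample is labelled as left quadriceps, although the right leg was the immobilized one. Replicate numbers in the text follow the order of the sample records only, and no sample was paired with another.

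The deposited values are raw counts per gene, 1 file per animal, with a merged table whose cells differed from the single files in 0 places. Per the labels' protocols, libraries were strand-specific and made from poly-A selected RNA, and were sequenced as paired ends. Trimmomatic, STAR 2.5, HTSeq 0.6.1p1 and DESeq2 are named with the genome build GRCm38, per the submitters' processing notes, which give the tools no role or order. The lines of each file that summarise reads assigned to no gene were set apart before any calculation. They held 9.33% of all entries, with reads that did not align uniquely between 3.92 and 6.65% per library. The annotation release is not stated. Of the 54446 gene identifiers, 53229 matched GENCODE M21 with their version and 54409 without it, and gene symbols and positions on GRCm38 were taken from that release. The names of 15 libraries end in the letter R, whose meaning is not stated. These were 1 young control, 6 CR, 4 IR, 3 CR plus IR and 1 animal of 76 weeks.

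Total counts per library ran from 11.0 to 27.45 M, with a median of 15.09 M, except for CR replicate 3, at 92.24 M. No 2 libraries were copies of each other: the smallest chi-square per degree of freedom between any pair was 4.7. Genes with too few counts were removed with filterByExpr, which left 13838 genes. Library sizes were scaled with TMM. Negative binomial quasi-likelihood models were fitted with edgeR 4.0.16 in R 4.3.3 to all 72 libraries at once, with 1 mean per group and 66 residual degrees of freedom, and 9 contrasts were tested with 2-sided tests. P-values were adjusted over all tested genes in each contrast with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale with their standard error (SE), positive where the first-named group was higher. The median SE was 0.13 to 0.132, except for the interaction, at 0.185. Expression levels are CPM, the count relative to the scaled library size, given as group means. Beside a gene's change, the number of animals is how many of the 12 in the first-named group lay on that side of the median of the other group.

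Before the data were examined, 43 gene lists, a panel of 18 muscle genes, the contrasts and the rule for naming genes were written down. Of the lists, 40 had at least 5 tested members. They cover protein breakdown and synthesis, energy metabolism, fibre type, innervation, matrix, stress responses, the clock, and markers of the other cell types that a muscle sample can hold. Lists were tested against all other genes with camera on voom values (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists. Camera was also run with a correlation estimated for each list, and fry was used to test whether the members of a list moved in 1 direction. A preset correlation gave many calls in random groupings of the same animals as well, so the p with an estimated correlation is printed beside each list that lost its call. The number of members called when p was adjusted over the list alone is given beside the number called over all genes.

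The genes named are the panel, the 6 genes with the highest and the 6 with the lowest change per comparison, and, for each list that camera called, up to 4 called members that moved with the list and 1 that moved against it. The highest and lowest were taken among called genes with a mean of at least 5 CPM and at least 10 of 12 animals on the same side. Genes known only by a number were left out. Any other named gene was chosen after its values were seen, and is marked so.

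The comparison of the interventions with ageing used the fold changes of all tested genes. All of these share the young controls, which makes them correlate by construction. Data without any difference between groups were therefore simulated 20 times to give the correlation and covariance that the shared controls alone produce. The young controls were also divided so that each side of the comparison had its own 6. The number of genes called in both of 2 comparisons was set against the number that the separate counts would give by chance.

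The pipeline was tested on simulated data made from the real means and library sizes, with 200 genes changed by a known factor. The denervation list was changed by the same factor, and genes with the lowest means were not among the 200. The adjusted threshold is stricter where fewer genes change, so the shares recovered hold for changes in about as many genes. For CR against control, 90.5% of the genes changed 2-fold were recovered, 63.5% of those changed 1.5-fold and 33% of those changed 1.25-fold. For the interaction the shares were 78.5%, 42.5% and 6.5%. Alternatives to the scaling, filter, tool, samples and covariates were run one at a time, as described in the closing section. They used DESeq2 1.42.0 and limma, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Transcript isoforms and reads outside genes were not analysed here.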

Results

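The series asked how muscle responded to 14 days of caloric restriction (CR), of immobilization of the right hindleg (IR), or of both together, as ways of inducing sarcopenia, the loss of muscle with age, and how these responses compared with ageing itself. Transcripts were counted in the quadriceps of 12 young controls, 12 CR, 12 IR and 12 CR plus IR animals aged 16 weeks, and of 12 animals of 76 weeks and 12 of 92 weeks. Total counts ran from 11.0 to 27.45 M per library, except for CR replicate 3, at 92.24 M. Group medians lay between 14.10 M at 76 weeks and 16.80 M after IR. All samples carry the label of the left quadriceps, so for the immobilized animals it is open whether the fixed leg was measured.

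Muscle fibre transcripts made up much of each library. The 10 genes with the highest counts, among them the fast myosin Myh4, the calcium pump Atp2a1 and the muscle actin Acta1, held 29.75 ± 1.51% of the counts in the young controls (SD, n = 12). Their share was 25.34 ± 1.81% under CR and 24.33 ± 2.07% under CR plus IR, against 28.55 ± 1.5% after IR, 28.49 ± 1.92% at 76 weeks and 27.63 ± 1.24% at 92 weeks. Fold changes are given relative to the typical gene, by TMM scaling. Scaling by library totals alone moved the median of all genes by 0.19 on the log2 scale for CR and 0.21 for CR plus IR against the controls, by 0.18 for CR plus IR against IR, by 0.02 at 76 weeks and by 0.05 at 92 weeks. The first component of a principal component analysis held 18.2% of the variance, the second 11.1% and the third 6.9%. CR plus IR replicate 9 stood apart, at 81.2 on the first component and 131.8 on the second. This library also had the fewest detected genes, 12598, and the lowest share of mitochondrially encoded counts, 3.73%. Without it, 6001 genes differed between CR plus IR and control, 5481 of them among the 5897 called with it.

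**Figure D1:**
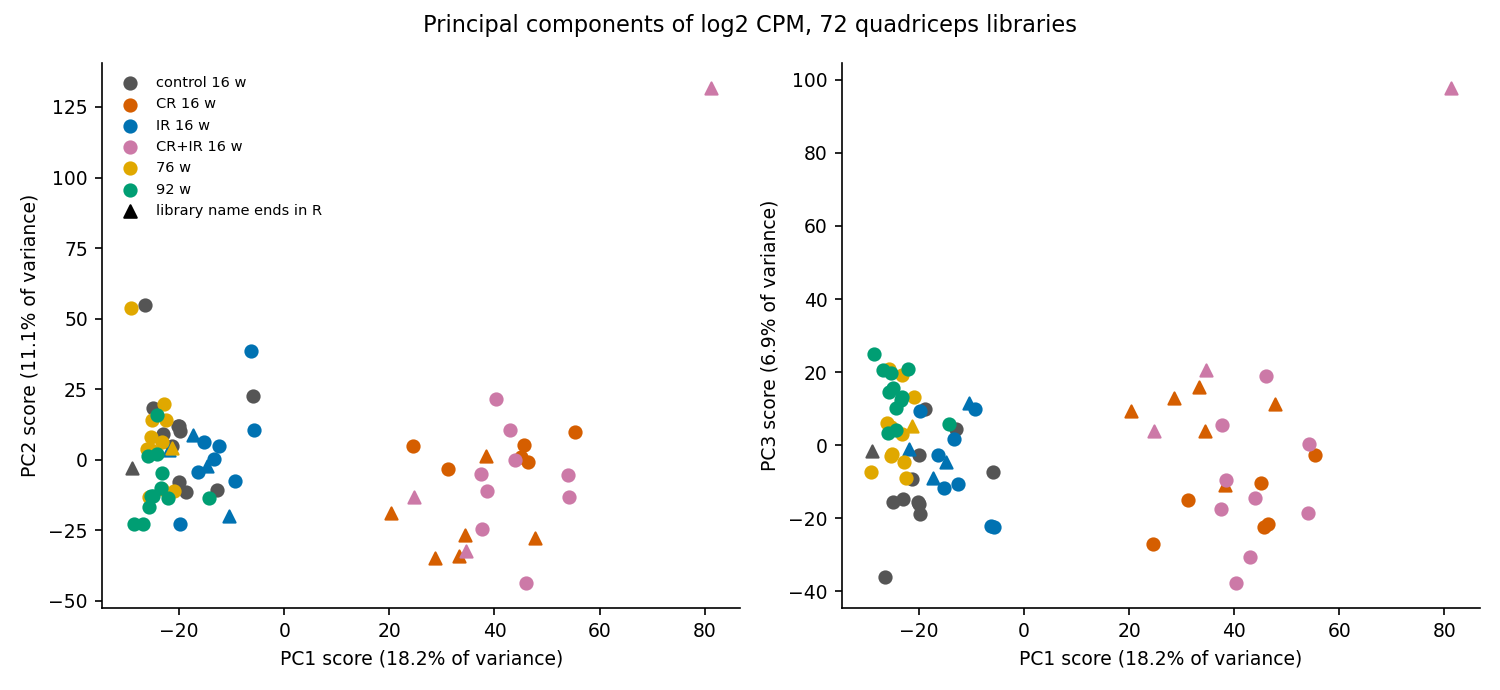
Each point is 1 library (n = 12 per group) placed by its first principal components of log2 CPM, with the share of variance on the axes (18.2 and 11.1%), and triangles mark the 15 libraries with names ending in R. CR plus IR replicate 9 lies at 81.2 on the first component.

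At an adjusted p under 0.05, 5357 of 13838 tested genes (38.7%) differed between CR and control, with 2773 higher and 2584 lower. For CR plus IR against control the numbers were 3065 higher and 2832 lower (42.6%). IR alone gave 1 higher and 2 lower. At 76 weeks 715 genes were higher and 598 lower than in the young controls (9.5%), and at 92 weeks 1164 were higher and 1048 lower (16%). With library totals in place of TMM, the split between higher and lower moved from 51.8% higher to 79.7% for CR (5203 and 1323), from 52% to 79.9% for CR plus IR (5721 and 1438), from 54.5% to 66.1% at 76 weeks (874 and 449) and from 52.6% to 70.5% at 92 weeks (1564 and 655).

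**Figure D2:**
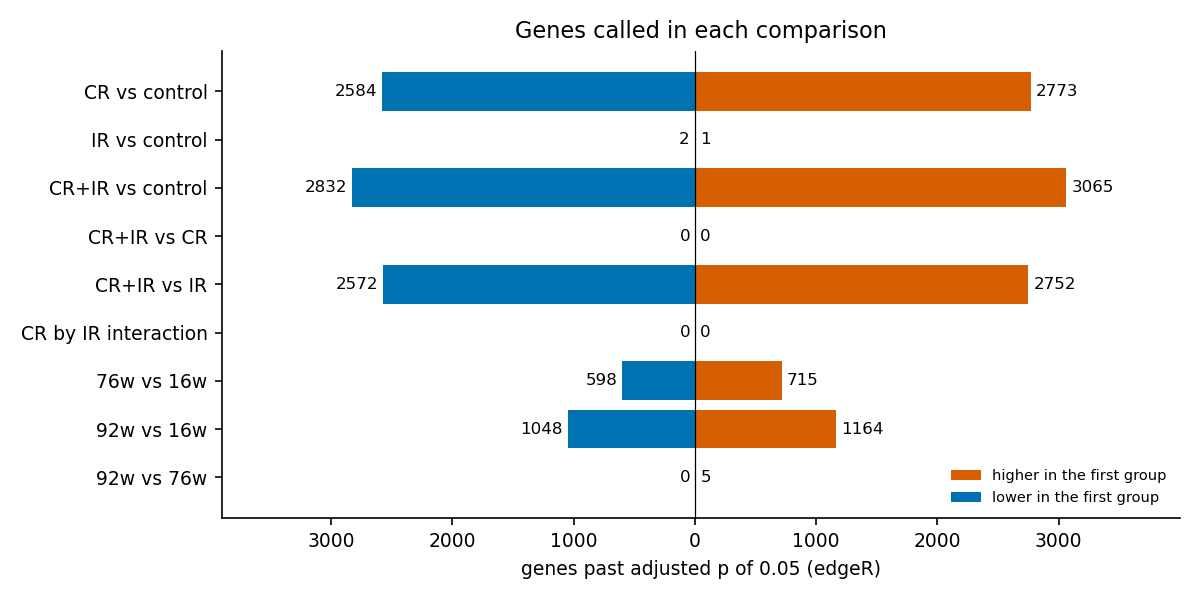
Bars give the number of genes higher and lower at an adjusted p under 0.05 in each of the 9 comparisons (13838 genes tested with edgeR, n = 12 animals per group). Against control, CR gave 5357 genes, CR plus IR 5897 and IR 3. With library totals in place of TMM, 79.7% of the CR calls were higher in place of 51.8%.

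Caloric restriction was compared with free feeding to see what fewer calories alone did. Transcripts of the fibrillar collagens showed some of the largest falls. Col3a1 (ENSMUSG00000026043.18, GRCm38 chromosome 1, 45311538 to 45349706) fell 11.9-fold, from 205 to 17.2 CPM (log2 fold change -3.57 ± 0.22, adjusted p = 1.1e-22, lower in 12 of 12 animals), and Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) fell 10.5-fold, from 104 to 9.84 CPM (-3.39 ± 0.27, adjusted p = 1.29e-17, 12 of 12). Of 71 ribosomal protein genes 70 rose, as did 18 of 21 glucocorticoid-responsive genes, while 17 of 23 genes of glycolysis and glycogen fell. With an estimated correlation these lists had an adjusted p of 0.194, 0.109 and 0.073. Among called genes with a mean of at least 5 CPM, the highest rise was that of Doc2b (ENSMUSG00000020848.7, chromosome 11, 75768966 to 75796049), a calcium sensor of vesicle fusion, at 21.1-fold (4.40 ± 0.48, adjusted p = 3.83e-12, 12 of 12). The largest fall among them was that of the cardiac actin Actc1 (ENSMUSG00000068614.7, chromosome 2, 114047282 to 114053548), from 252 to 17.1 CPM (-3.88 ± 0.32, 12 of 12). Also among the 6 highest were Cdhr3 (3.86) and Egln3 (3.22), and among the 6 lowest Nrep (-2.98), Dkk3 (-2.92) and Aplnr (-2.81). Unless another number is given, each gene named as higher or lower under CR was so in 12 of 12 animals.

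Among the 27 tested extracellular matrix genes, 26 fell under CR and 0 rose, over all genes as adjusted over the list alone. Their median was -1.29 (camera adjusted p = 1.92e-24, and adjusted p = 0.0458 with an estimated correlation). Besides the 2 collagens above, Col1a2 changed by -2.41 ± 0.19, Col6a3 by -1.81 ± 0.13 and Sparc, a protein that binds collagen, by -1.32 ± 0.10. Tenocyte markers moved with them: of 10 tested, 8 fell and 1 rose, with the same numbers adjusted over the list alone (median -2.08, adjusted p = 0.0219, but adjusted p = 0.749 with an estimated correlation). Chad fell by 3.22 ± 0.61, Comp by 2.48 ± 0.48 and Fmod by 1.74 ± 0.38 on the log2 scale, all 3 matrix proteins of tendon or cartilage, while Scx, the transcription factor of the tendon lineage, rose by 0.85 ± 0.21. With the mean level of the tenocyte markers, a list that holds them, as a covariate, Chad was at -0.24, Comp at -0.48 and Fmod at -0.05, and none of these passed. With the level of Arntl, a core clock gene, as a covariate Scx did not pass (0.67, adjusted p = 0.1, range over all alternatives 3.78e-06 to 0.1), nor did Comp (-1.30) and Fmod (-0.67). Of 12 markers of fibro-adipogenic progenitors, the stromal cells that make much of the muscle matrix, 6 fell and 0 rose by either adjustment (median -0.35, adjusted p = 0.00386, and adjusted p = 0.525 with an estimated correlation). Examples were Pi16 at -1.66 ± 0.20 and Dpt at -1.08. With the tenocyte covariate, the median of the extracellular matrix list was -0.99 and 22 of its members fell.

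Ribosomal protein genes rose almost as a whole under CR: 70 of 71 over all genes and 71 adjusted over the list alone, with 0 lower (median 0.55, camera adjusted p = 1.43e-29, and adjusted p = 0.194 with an estimated correlation). Rpl3 (ENSMUSG00000060036.14, chromosome 15, 80077791 to 80091868) rose from 35 to 92.3 CPM (1.40 ± 0.10, adjusted p = 9.91e-20), Rpl12 by 0.98 ± 0.09 and Rpl4 by 0.59 ± 0.06. Of 21 glucocorticoid-responsive genes, 18 rose and 0 fell, or 19 and 1 adjusted over the list alone (median 1.19, adjusted p = 4.22e-10, and adjusted p = 0.109 with an estimated correlation). They include Arrdc2, at 14.1 CPM in controls and 128 under CR (3.18 ± 0.26), the metallothioneins Mt2 at 3.03 ± 0.45 and Mt1 at 2.82 ± 0.28, the transcription factor Cebpd at 2.96 ± 0.29, and Fkbp5, a co-chaperone of the glucocorticoid receptor, at 1.41 ± 0.16. Of 18 FoxO and fasting targets, which share 6 genes with the glucocorticoid list (Ddit4 among them), 11 rose and 0 fell by either adjustment (median 0.37, adjusted p = 0.00119, and adjusted p = 0.377 with an estimated correlation). They included Eif4ebp1, an inhibitor of translation, at 1.63 ± 0.14 and Ddit4, an inhibitor of mTORC1, at 2.62 ± 0.38. Of 34 proteasome subunits, 15 rose and 1 fell, or 16 and 2 adjusted over the list alone (median 0.15, adjusted p = 0.00915, and adjusted p = 0.768 with an estimated correlation). Psma7 rose by 0.71 and Psmd2 by 0.55 (11 of 12), and Psma1 fell by 0.29 on the log2 scale, but was at -0.10 with library totals (adjusted p = 0.263, range over all alternatives 1.33e-05 to 0.263). The ubiquitin ligases of muscle atrophy did not move as a list, with 4 of 17 higher and 6 lower by either adjustment (adjusted p = 0.391).

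Of 23 tested genes of glycolysis and glycogen, 17 fell and 3 rose by either adjustment (median -0.57, camera adjusted p = 2.71e-09, and adjusted p = 0.073 with an estimated correlation). Pgam2, the muscle phosphoglycerate mutase, changed by -1.33 ± 0.11, Eno3 by -1.11, Pkm by -0.86 and Pfkm by -0.86 ± 0.06, and Gyg, the primer of glycogen synthesis, rose by 0.58. Of 21 genes of the TCA cycle, 16 fell and 1 rose by either adjustment (median -0.25, adjusted p = 4.55e-05, and adjusted p = 0.579 with an estimated correlation). Among them were Sucla2 at -0.49 ± 0.05 and Idh3a at -0.42, but with library totals the median of the TCA cycle was -0.05 and 5 fell. Among the 12 mitochondrially encoded genes, 9 fell and 0 rose by either adjustment (median -0.34, adjusted p = 0.00386, and adjusted p = 0.68 with an estimated correlation), but with library totals the median was -0.15 and 2 fell. The nuclear subunits of complex I (35 tested, 12 lower and 1 higher by either adjustment, median -0.14, adjusted p = 0.0237, and adjusted p = 0.768 with an estimated correlation) had a median of 0.05 with library totals. The nuclear subunits of complexes II to V (38 tested, 12 lower and 2 higher by either adjustment, median -0.16, adjusted p = 0.0188, and adjusted p = 0.768 with an estimated correlation) had a median of 0.03, so the direction of both turned with the scaling. Fatty acid synthesis went the other way. Of 16 genes, 8 rose and 1 fell, or 10 and 1 adjusted over the list alone (median 0.42, adjusted p = 0.0113, and adjusted p = 0.768 with an estimated correlation). Examples were Elovl6 from 3.09 to 58.2 CPM (4.21 ± 0.63), Acly from 27.3 to 262 CPM (3.26 ± 0.47), Scd1 at 3.15 ± 0.58 and Acaca at 2.45 ± 0.37. Without the libraries whose names end in R, of which CR holds 6, these ranged from 2.98 for Elovl6 to 1.55 for Acaca, each with an adjusted p of at most 0.00822, and 5 of the genes of fatty acid synthesis rose (median 0.20). With the Arntl covariate Scd1 was at 1.56 and lost its call (adjusted p = 0.161, range over all alternatives 4.6e-12 to 0.161). In the same fit Elovl6 was at 2.64, Acly at 2.10 and Acaca at 1.49, with an adjusted p of at most 0.0358.

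Of 12 adipocyte markers, 10 rose and 0 fell by either adjustment (median 1.32), although camera did not call the list (adjusted p = 0.0943). Without the R libraries their median was 0.21 and 1 rose, and with Arntl as a covariate it was -0.08 and 0 rose. With the mean level of the adipocyte markers as a covariate, Elovl6 was at 2.84, Acly at 1.97 and Scd1 at 1.73, with an adjusted p of at most 4.6e-12.

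Of 14 fast fibre genes, 9 fell and 2 rose under CR by either adjustment (median -0.43, camera adjusted p = 3.6e-05, and adjusted p = 0.335 with an estimated correlation). The light chain Myl1 fell from 9220 to 2720 CPM (-1.76 ± 0.12), Casq1, which binds calcium in the sarcoplasmic reticulum, changed by -1.16, and Pvalb by -1.06. Of 16 heat shock and chaperone genes, 7 fell and 2 rose by either adjustment (median -0.30, adjusted p = 0.00621, and adjusted p = 0.377 with an estimated correlation). Hspa8 fell from 1040 to 435 CPM (-1.26 ± 0.08), and Hsf1, the transcription factor of the heat shock response, rose by 0.62. Of 12 polyamine genes, 7 fell and 3 rose by either adjustment (median -0.32, adjusted p = 0.00309, and adjusted p = 0.0458 with an estimated correlation). Amd1 (ENSMUSG00000075232.5, chromosome 10, 40287458 to 40302186), which makes the donor for spermidine and spermine, fell from 1470 to 246 CPM (-2.58 ± 0.17), and the spermine oxidase Smox from 652 to 144 CPM (-2.18 ± 0.21). Of 12 antigen presentation genes, 7 fell and 0 rose by either adjustment (median -0.79, adjusted p = 0.000833, and adjusted p = 0.378 with an estimated correlation). Among these were the class II genes H2-Ab1 at -2.07 ± 0.22 and Cd74 at -1.91 ± 0.20.

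Of the 18 panel genes, 7 rose and 4 fell under CR. Besides Fkbp5, these were Foxo1 (0.92 ± 0.16), the cell cycle inhibitor Cdkn1a (0.90 ± 0.23), the acetylcholine receptor subunit Chrna1 (0.72 ± 0.14, 11 of 12 animals), myostatin (Mstn, 0.36 ± 0.12, adjusted p = 0.014, 9 of 12) and the myosins Myh2 (1.28 ± 0.38, adjusted p = 0.00522, 10 of 12) and Myh1 (0.92 ± 0.22, adjusted p = 0.00044). Myh4 (-0.58 ± 0.10), the growth factor Igf1 (-1.10 ± 0.18), Col1a1 and Col3a1 fell. The atrophy ligases Fbxo32 (0.16 ± 0.22, adjusted p = 0.62, 7 of 12) and Trim63 (0.01 ± 0.23, adjusted p = 0.971, 5 of 12) did not pass. Neither did Pdk4 (-0.12, 7 of 12 lower), Ppargc1a (-0.14, 7 of 12 lower), Myog (0.02, 5 of 12 higher), Ncam1 (0.18, 9 of 12 higher) and Myh7 (0.61 ± 0.80, 9 of 12 higher). Ncam1 passed with library totals (0.38, adjusted p = 0.0215, range over all alternatives 0.0215 to 0.456) and Fbxo32 with the Arntl covariate (0.94, adjusted p = 0.0261, range 0.0261 to 0.824). Without the R libraries Myh2 was at 0.48 (adjusted p = 0.446, range over all alternatives 0.00121 to 0.446) and Myh1 at 0.54 (adjusted p = 0.0986, range 2.41e-05 to 0.0986), and neither passed with the Arntl covariate (0.83 and 0.79). Without the R libraries 4690 genes were called, 4057 of them among the 5357. With the level of Arntl as a covariate, 3371 genes were called under CR.

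**Figure D3:**
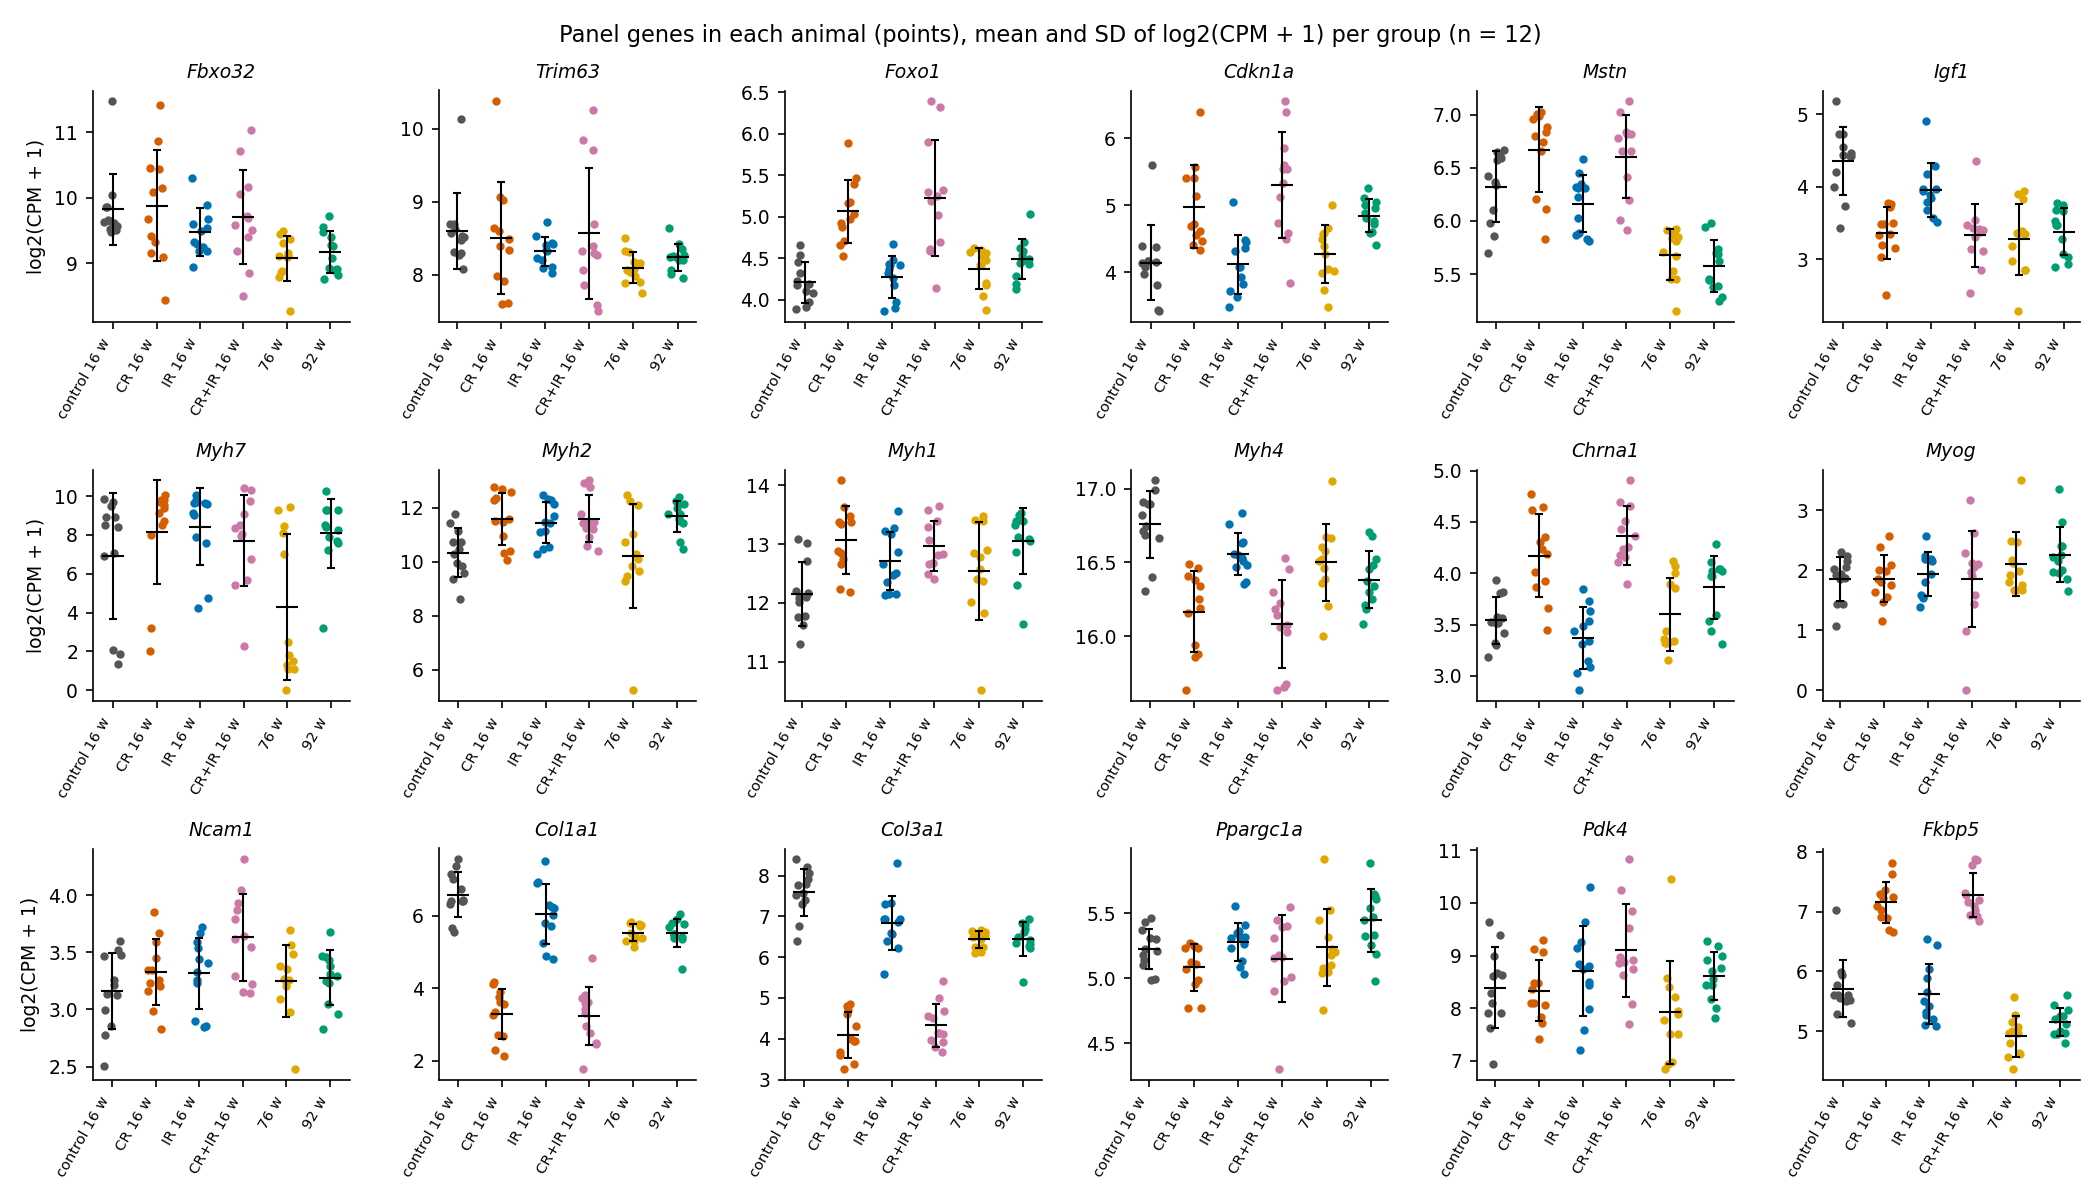
Points are animals, with the mean and SD (n = 12) of log2 (CPM + 1), for the panel genes in the 6 groups. Col3a1 had a mean of 205 CPM in the young controls, 17.2 under CR and 20.4 under CR plus IR.

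Immobilization alone was compared with the controls to see what disuse did. It left few marks in these samples, which carry the label of the left quadriceps while the right leg was fixed. At an adjusted p under 0.05, 3 genes differed: Gpalpp1 (ENSMUSG00000022008.4, chromosome 14, 76086236 to 76110760) rose from 11.7 to 16.4 CPM (0.49 ± 0.08, adjusted p = 0.00161, 12 of 12 animals), the minor collagen Col5a3 (ENSMUSG00000004098.7, chromosome 9, 20770050 to 20815067) fell from 53.4 to 34.2 CPM (-0.65 ± 0.13, adjusted p = 0.0241, 11 of 12), and Mettl21c (ENSMUSG00000047343.4, chromosome 1, 44009408 to 44020034), a methyltransferase of muscle, fell from 75.3 to 43.5 CPM (-0.79 ± 0.15, adjusted p = 0.0158, 11 of 12). An unadjusted p under 0.05 was reached by 983 genes. In simulated data for IR, 65% of genes changed 1.5-fold and 91% of those changed 2-fold were recovered. Of the genes with the smallest simulated change, below 1.5-fold, 30.5% were recovered.

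None of the panel genes passed after IR. Fbxo32 was at -0.44 ± 0.23 (adjusted p = 0.732, 9 of 12 animals lower), Trim63 at -0.38 (adjusted p = 0.8, 11 of 12 lower), Col3a1 at -0.71 ± 0.20 (adjusted p = 0.328, or 0.0186 with limma voom and quality weights, range over all alternatives 0.0186 to 0.522, 11 of 12 lower) and Myh2 at 1.05 ± 0.38 (adjusted p = 0.526, 11 of 12 higher). The list of denervation and neuromuscular junction genes had a median of 0.04, with 0 of 21 called by either adjustment, and the ubiquitin ligases of atrophy a median of 0.01 with 0 of 17 called.

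Camera nevertheless called 14 lists after IR, of which the extracellular matrix kept its call with an estimated correlation. Of its 27 genes, 0 passed over all genes and 12 fell adjusted over the list alone (median -0.37, adjusted p = 9.65e-25, and adjusted p = 0.0489 with an estimated correlation). Along with it went the fibro-adipogenic progenitor markers (0 passed over all genes and 3 fell adjusted over the list alone, median -0.24, adjusted p = 0.239 with an estimated correlation), antigen presentation (0 and 4 likewise, median -0.28, adjusted p = 0.258 with an estimated correlation), tenocyte markers (0 by either adjustment, median -0.39, adjusted p = 0.697 with an estimated correlation) and macrophage markers (0 by either adjustment, median -0.39, adjusted p = 0.339 with an estimated correlation). Fatty acid oxidation had a median of 0.21 (0 of 28 called by either adjustment, adjusted p = 4.74e-10, and adjusted p = 0.339 with an estimated correlation) and the slow fibre genes one of 0.54 (0 of 12, adjusted p = 2.53e-06, and adjusted p = 0.354 with an estimated correlation). The other 7 lists had medians between -0.14 and 0.13, with at most 1 member called adjusted over the list alone and an adjusted p of 0.145 or more with an estimated correlation. Col5a3 and Mettl21c stayed near their size but lost their calls without the R libraries (-0.55 and -0.78, adjusted p = 0.225 for both, the highest over all alternatives, with 0.000896 and 0.00121 the lowest), in a fit of only the groups compared (-0.65 and -0.80, adjusted p = 0.104 and 0.0995) and with Arntl as a covariate (-0.63 and -0.77, adjusted p = 0.0781 and 0.067). Col5a3 also lost its call with library totals (-0.61, adjusted p = 0.0529) and with the slow fibre genes as a covariate (-0.62, adjusted p = 0.0607).

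Both interventions together were compared with the controls to see the combined model. Of 27 extracellular matrix genes 24 fell, as did 10 of 14 fast fibre genes, while 68 of 71 ribosomal protein genes and 18 of 21 glucocorticoid-responsive genes rose. With an estimated correlation none of these lists was called (adjusted p = 0.0889, 0.221, 0.221 and 0.0889). Col3a1 fell 10.1-fold, to 20.4 CPM (-3.33 ± 0.22, adjusted p = 1.62e-21), and Col1a1 changed by -3.39 ± 0.27. Doc2b rose 44.6-fold (5.48 ± 0.49), followed by Aspg at 4.87 ± 0.71 (11 of 12 animals), Elovl6 at 4.62 ± 0.63, Cdhr3 at 3.97 ± 0.30 and Depp1, a FoxO target, at 3.77 ± 0.42. The lowest besides Col1a1 and Col3a1 were Aplnr, the apelin receptor, at -3.47 ± 0.29, Nrep at -3.31 ± 0.20, Actc1 at -3.25 ± 0.31 and Col15a1, a minor collagen, at -2.75 ± 0.21. Without CR plus IR replicate 4, Aspg was at 3.32 and Elovl6 at 3.61, and with Arntl as a covariate Aspg did not pass (2.82, adjusted p = 0.0928, range over all alternatives 1.63e-11 to 0.0928). Unless another number is given, 12 of 12 animals shared the direction of each gene named as higher or lower, and a list given with 1 set of counts had the same ones adjusted over the list alone.

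Of the 27 extracellular matrix genes, 24 fell and 0 rose under both interventions by either adjustment (median -1.29, camera adjusted p = 8.4e-22, and adjusted p = 0.0889 with an estimated correlation). Tenocyte markers fell beside them (8 of 10 lower and 1 higher, or 9 and 1 adjusted over the list alone, median -1.75, adjusted p = 0.0163, and adjusted p = 0.755 with an estimated correlation), as did those of fibro-adipogenic progenitors (6 of 12 lower by either adjustment, median -0.51, adjusted p = 0.00187, and adjusted p = 0.497 with an estimated correlation). Of 71 ribosomal protein genes, 68 rose and 0 fell, or 69 adjusted over the list alone (median 0.51, adjusted p = 8.54e-25, and adjusted p = 0.221 with an estimated correlation). Among them was Rpl3 at 1.31 ± 0.10. Glucocorticoid-responsive genes rose in 18 of 21 cases by either adjustment (median 1.32, adjusted p = 1.1e-12, and adjusted p = 0.0889 with an estimated correlation). Examples were Arrdc2 at 3.57 ± 0.27 and Cebpd at 3.14. FoxO and fasting targets rose in 12 of 18 cases, or 13 adjusted over the list alone (median 0.75, adjusted p = 4.16e-05, and adjusted p = 0.221 with an estimated correlation). Ddit4 was at 3.42 ± 0.38. Proteasome subunits rose in 15 of 34 cases and fell in 1, or 16 and 1 adjusted over the list alone (median 0.13, adjusted p = 0.00375, and adjusted p = 0.755 with an estimated correlation).

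Glycolysis and glycogen genes fell in 16 of 23 cases and rose in 3 by either adjustment (median -0.50, adjusted p = 8.86e-08, and adjusted p = 0.11 with an estimated correlation). Among them were Pgam2 at -1.36 and Pkm at -0.88. Fast fibre genes fell in 10 of 14 cases and rose in 2 (median -0.49, adjusted p = 4.48e-06, and adjusted p = 0.221 with an estimated correlation). Examples were Myl1 at -1.73 ± 0.12 and Casq1 at -1.23. The TCA cycle list (12 of 21 lower and 1 higher, median -0.16, adjusted p = 0.00663, and adjusted p = 0.755 with an estimated correlation) turned to a median of 0.04 with library totals, when 2 fell. Mitochondrially encoded genes fell in 8 of 12 cases (median -0.32, adjusted p = 0.0183, and adjusted p = 0.755 with an estimated correlation), but with library totals the median was -0.12 and 1 fell, and without the R libraries 4 fell. Heat shock genes fell in 8 of 16 cases and rose in 3 (median -0.32, adjusted p = 0.0129, and adjusted p = 0.492 with an estimated correlation). Hspa8 was at -1.31 ± 0.08, and with library totals 5 of the list fell (median -0.11). Polyamine genes fell in 7 of 12 cases and rose in 3 (median -0.31, adjusted p = 0.014, and adjusted p = 0.11 with an estimated correlation). Amd1 was at -2.60 ± 0.17. Antigen presentation genes fell in 6 of 12 cases (median -0.57, adjusted p = 0.00463, and adjusted p = 0.552 with an estimated correlation). H2-Aa was at -2.05. Fatty acid synthesis genes rose in 9 of 16 cases and fell in 1, or 10 and 1 adjusted over the list alone (median 0.70, adjusted p = 0.0103, and adjusted p = 0.755 with an estimated correlation). Acly was at 3.54 ± 0.47, Scd1 at 3.45 and Acaca at 2.73. With Arntl as a covariate Acly was at 2.13 (adjusted p = 0.0363, range over all alternatives 1.84e-14 to 0.0363). In that fit Scd1 (1.52, adjusted p = 0.257, range 6.04e-13 to 0.257) and Acaca (1.58, adjusted p = 0.0549, range 1.02e-12 to 0.0549) lost their calls. With the adipocyte covariate Elovl6 was at 2.86, Acly at 1.91, Scd1 at 1.80 and Acaca at 1.54, each called. Without CR plus IR replicate 4 Acly was at 2.71, Scd1 at 2.65 and Acaca at 2.10, and the median of the list was 0.39, with 8 higher and 2 lower. Beside them 10 of 12 adipocyte markers rose by either adjustment (median 1.64, adjusted p = 0.0517), with 1.66 without the R libraries, 0.83, with 6 higher, without CR plus IR replicate 4, and 0.03, with 1 higher, with Arntl as a covariate. Among the adipocyte markers, Cidea rose by 3.57 ± 0.76 (11 of 12 animals), with a median of 2.85 CPM and a mean of 11.2 CPM that holds 83.1 CPM in replicate 4. It was at 2.30 without that animal and at 0.50 with Arntl as a covariate (adjusted p = 0.836, range over all alternatives 1.62e-05 to 0.836).

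Of the 18 panel genes, 9 rose and 4 fell under both interventions. Fkbp5 (1.54 ± 0.16), Cdkn1a (1.28 ± 0.23, 11 of 12 animals), Foxo1 (1.20 ± 0.16, 11 of 12), Chrna1 (0.89 ± 0.14), Ncam1 (0.53 ± 0.14, adjusted p = 0.00113, 10 of 12), Myh2 (1.28 ± 0.38, adjusted p = 0.00451), Myh1 (0.77, adjusted p = 0.00298), Pdk4 (0.80 ± 0.31, adjusted p = 0.0342, 10 of 12) and Mstn (0.30, adjusted p = 0.0429, 9 of 12, range over all alternatives 2.3e-05 to 0.203) rose. Igf1 (-1.10), Myh4 (-0.67 ± 0.10), Col1a1 and Col3a1 fell. Fbxo32 (-0.08, adjusted p = 0.802, 6 of 12 lower) and Trim63 (0.14, adjusted p = 0.656, 4 of 12 higher) did not pass. Neither did Myh7 (0.29 ± 0.79, 5 of 12 higher), Myog (0.19, 7 of 12 higher) and Ppargc1a (-0.05, 7 of 12 lower). Pdk4 lost its call at about the same size without young control replicate 5 (0.76, adjusted p = 0.0523) and without the R libraries (0.81, adjusted p = 0.0546). It was at 0.66 with the tenocyte covariate (adjusted p = 0.156), at 0.68 with the adipocyte covariate (adjusted p = 0.0595) and at -0.01 with Arntl as a covariate (adjusted p = 0.996, range over all alternatives 0.00667 to 0.996). With the Arntl covariate Myh2 (0.80, adjusted p = 0.387, range 0.000995 to 0.387) and Myh1 (0.63, adjusted p = 0.218, range 0.000161 to 0.218) did not pass either. In that fit 3045 genes were called for both interventions against control.

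**Figure D4:**
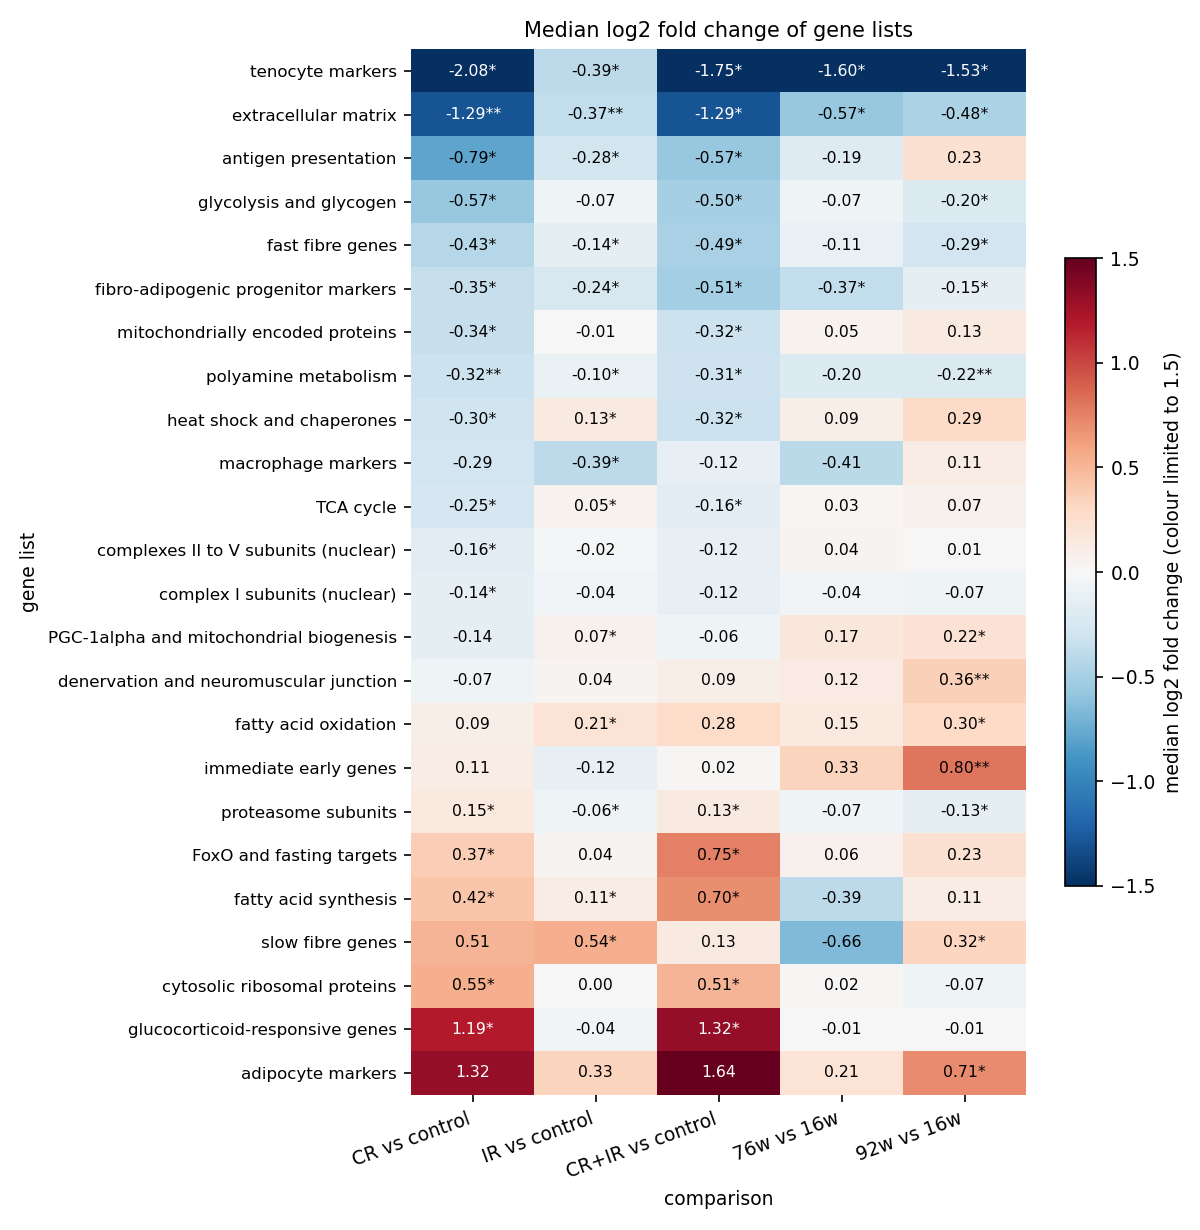
Colour gives the median log2 fold change (limited to 1.5) of each gene list in each comparison, 1 star a camera adjusted p under 0.05 and 2 stars a call that held with an estimated correlation (n = 12 per group). The extracellular matrix list had a median of -1.29 under CR. Under CR with library totals, the complex I and complexes II to V lists turned to 0.05 and 0.03, and under CR plus IR the TCA cycle list turned to 0.04.

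What immobilization added to CR was tested in 2 ways. Between CR plus IR and CR, edgeR called 0 genes, with 800 at an unadjusted p under 0.05, and DESeq2 and limma voom with quality weights also called 0. Pdk4, which spares glucose by holding back pyruvate oxidation, was at 0.92 ± 0.32 (adjusted p = 0.628, 10 of 12 animals higher) and Ncam1, a marker of denervated fibres, at 0.35 ± 0.14 (adjusted p = 0.736, 8 of 12). Camera called fatty acid oxidation (median 0.10, adjusted p = 7.46e-05), glucocorticoid-responsive genes (0.21, adjusted p = 0.000226), the TCA cycle (0.04, adjusted p = 0.00182) and FoxO targets (0.10, adjusted p = 0.00558), with 0 members called over all genes and 1, in fatty acid oxidation, adjusted over the list alone. All 4 had an adjusted p of 0.925 with an estimated correlation.

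The interaction asked whether IR acted differently under CR than under free feeding. edgeR called 0 genes, with 775 at an unadjusted p under 0.05 and a smallest adjusted p of 0.54, and DESeq2 and limma voom with quality weights also called 0. Col3a1 was at 0.95 ± 0.29 (adjusted p = 0.56) and Myh2 at -1.04 ± 0.53 (adjusted p = 0.881). Extracellular matrix genes had a median of 0.30 (0 called over all genes and 2 higher adjusted over the list alone, camera adjusted p = 6.14e-09, and adjusted p = 0.74 with an estimated correlation). Slow fibre genes had a median of -0.85 (0 called, adjusted p = 8.78e-05, and adjusted p = 0.74 with an estimated correlation), which turned to 0.15 without the R libraries. Antigen presentation (0.29), polyamine (0.18), proteasome (0.06) and glycolysis (0.06) were the other lists called, and their adjusted p was 0.279 or more with an estimated correlation. The glycolysis median turned to -0.05 without the R libraries. In simulated data, 42.5% of genes with an interaction of 1.5-fold and 78.5% of those of 2-fold were recovered.

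What CR added to immobilization was measured between CR plus IR and IR, with 2752 genes higher and 2572 lower (51.7% higher, or 78.7% with library totals, 4972 and 1343). Doc2b rose by 5.76 ± 0.50, Cdhr3 by 3.80 ± 0.30, Ddit4 by 3.60 ± 0.39, Depp1 by 3.39 ± 0.40 and Arrdc2 by 3.32 ± 0.26 in 12 of 12 animals. Aspg rose by 3.58 ± 0.64 (10 of 12 animals), but was at 2.02 without CR plus IR replicate 4 and at 1.93 with Arntl as a covariate (adjusted p = 0.171, range over all alternatives 1.01e-06 to 0.171). Aplnr changed by -3.29 ± 0.29, Nmrk2, a kinase of NAD synthesis, by -3.09 ± 0.32 (from 142 to 16.6 CPM), Col1a1 by -2.94 ± 0.27, Nrep by -2.71 ± 0.20, Actc1 by -2.67 ± 0.30 and Col3a1 by -2.62 ± 0.21, all in 12 of 12 animals. A list given with 1 set of counts had the same ones adjusted over the list alone. Ribosomal protein genes rose in 69 of 71 cases (median 0.48, camera adjusted p = 4.9e-28, and adjusted p = 0.225 with an estimated correlation) and glucocorticoid-responsive genes in 18 of 21 (1.36, adjusted p = 9.5e-15, and adjusted p = 0.0834 with an estimated correlation). Extracellular matrix genes fell in 22 of 27 cases, or 23 with 1 higher adjusted over the list alone (-0.88, adjusted p = 3.12e-14, and adjusted p = 0.188 with an estimated correlation). Proteasome subunits rose in 21 of 34 cases and fell in 1 (0.19, adjusted p = 1.77e-05, and adjusted p = 0.603 with an estimated correlation), and FoxO targets rose in 11 of 18 (0.43, adjusted p = 0.000101, and adjusted p = 0.226 with an estimated correlation). Glycolysis genes fell in 16 of 23 cases and rose in 3, or 17 and 3 adjusted over the list alone (-0.50, adjusted p = 2.87e-07, and adjusted p = 0.188 with an estimated correlation), and fast fibre genes fell in 10 of 14 (-0.40, adjusted p = 0.226 with an estimated correlation). So did TCA cycle genes in 16 of 21 with 1 higher (-0.22, adjusted p = 0.603 with an estimated correlation, and -0.04 with 4 lower with library totals), heat shock genes in 11 of 16 with 1 higher, or 3 higher adjusted over the list alone (-0.44, adjusted p = 0.188 with an estimated correlation) and mitochondrially encoded genes in 8 of 12 (-0.31, adjusted p = 0.732 with an estimated correlation, and -0.14 with 0 lower with library totals). With Arntl as a covariate, 3355 genes were called.

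Ageing to 76 weeks was compared with the young controls to give a reference for natural muscle ageing. Ostn (ENSMUSG00000052276.8, chromosome 16, 27307489 to 27351212), which encodes the secreted peptide osteocrin, rose 5.09-fold, from 3.93 to 20 CPM (2.35 ± 0.24, adjusted p = 4.02e-11), and the amylase gene Amy1 from 35.7 to 94.8 CPM (1.41 ± 0.09, adjusted p = 5.01e-21). Prg4 (ENSMUSG00000006014.16, chromosome 1, 150449412 to 150466165), the lubricin of joints and tendons, fell 7.11-fold (-2.83 ± 0.49, adjusted p = 3.22e-05), Actc1 from 252 to 55.4 CPM (-2.19 ± 0.29) and the non-coding RNA Rian by 1.44 ± 0.22 on the log2 scale. These moved in 12 of 12 animals. Also among the 6 highest were Katnal2 (1.55 ± 0.23), Srrm4os (1.52 ± 0.21), Pkp2 (1.45 ± 0.17) and Cmss1 (1.61 ± 0.26, 11 of 12 animals), whose mean of 396 CPM (SD 499) holds 1920 CPM in replicate 7, without which it was at 0.99 (adjusted p = 0.000285, range over all alternatives 3.2e-07 to 0.00163). Angptl7 was among the lowest (-2.01, 11 of 12 animals). Age and cohort cannot be separated here.

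Matrix genes were lower at 76 weeks. Of 27 extracellular matrix genes, 16 fell and 0 rose, or 21 adjusted over the list alone (median -0.57, camera adjusted p = 1.08e-18, and adjusted p = 0.143 with an estimated correlation). Among them were Col3a1 at -1.25 ± 0.20, Col1a1 at -1.18 ± 0.25, Col1a2 at -1.17 and Sparc at -0.72. Of 10 tenocyte markers, 7 fell and 0 rose, or 9 adjusted over the list alone (median -1.60, adjusted p = 8.81e-05, and adjusted p = 0.373 with an estimated correlation). Examples were Chad at -2.39, Fmod at -1.83 ± 0.39 and Comp at -1.58 ± 0.46 (11 of 12 animals). Of 12 markers of fibro-adipogenic progenitors, 5 fell and 0 rose, or 9 adjusted over the list alone (median -0.37, adjusted p = 8.81e-05, and adjusted p = 0.373 with an estimated correlation). They included Lum at -0.58 and Dcn at -0.40, and without the R libraries 3 fell and Lum was at -0.54 (adjusted p = 0.0503, range over all alternatives 0.00127 to 0.475). With the tenocyte markers as a covariate, the median of the extracellular matrix list was -0.27, 4 of its members fell, and Col1a1 no longer passed (-0.44, adjusted p = 0.153, range over all alternatives 8e-07 to 0.153), nor did Chad (-0.20), Fmod (-0.35), Comp (-0.02), Angptl7 (-0.44), Lum (-0.22) and Dcn (-0.10). With Arntl as a covariate, Comp (-1.17), Lum (-0.50) and Dcn (-0.27) did not pass.

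Of the panel, 0 genes rose and 6 fell at 76 weeks: Igf1 (-1.16 ± 0.18, adjusted p = 2.84e-06), Mstn (-0.66 ± 0.12, adjusted p = 0.000134), Fkbp5 (-0.87 ± 0.16, adjusted p = 0.00014), Fbxo32 (-0.84 ± 0.23, adjusted p = 0.00981), Col1a1 and Col3a1, each in 12 of 12 animals. Trim63 (-0.60, adjusted p = 0.083) and Myh4 (-0.25, adjusted p = 0.0863, 11 of 12 lower) did not pass, though both did under some alternatives (adjusted p from 0.00968 to 0.349 and from 0.00487 to 0.193). Without young control replicate 11, which had 2850 CPM of Fbxo32 and 1130 CPM of Trim63, Fbxo32 was at -0.57 (adjusted p = 0.0695, range over all alternatives 0.00181 to 0.172).

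Animals of 92 weeks were compared with the same young controls. Of 13 immediate early genes 9 rose, of 28 genes of fatty acid oxidation 14 and of 21 genes of denervation and the neuromuscular junction 8, while 15 of 27 extracellular matrix genes and 5 of 12 polyamine genes fell. With an estimated correlation the adjusted p of these lists was 0.0332, 0.567, 0.0449, 0.294 and 0.018. Ostn rose again (2.27 ± 0.24, 4.82-fold, adjusted p = 7.41e-11), as did Prkcz (2.26 ± 0.24), Rrad, a small GTPase that holds back calcium channels (2.17 ± 0.39), Cyfip2 (3.22 ± 0.53) and Tmem45b (2.08 ± 0.65, 11 of 12 animals). Gpnmb (ENSMUSG00000029816.10, chromosome 6, 49036546 to 49070929), a glycoprotein of macrophages, was highest among called genes with a mean of at least 5 CPM, at 3.28 ± 0.54 (adjusted p = 6.09e-06, 11 of 12), with a mean of 23.3 CPM (SD 45.9) that holds 158 CPM in replicate 8, without which it was at 2.20 (adjusted p = 0.00041). The lowest were Prg4 (-2.46 ± 0.48), Actc1 (-2.15 ± 0.29, from 252 to 57 CPM), Fmod (-1.76), Angptl7 (-1.54 ± 0.47), Comp (-1.52 ± 0.46) and Smox (-1.38 ± 0.20). With the tenocyte markers as a covariate, Angptl7 was at 0.23, Comp at 0.12 and Fmod at -0.33, none of which passed, and Tmem45b was at 1.91 (adjusted p = 0.0503, range over all alternatives 0.00163 to 0.0503).

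Of 13 immediate early genes, 9 rose and 0 fell at 92 weeks, or 11 adjusted over the list alone (median 0.80, camera adjusted p = 4.54e-07, and adjusted p = 0.0332 with an estimated correlation). Among these were the stress-induced Atf3 at 1.79 ± 0.35, Egr1 at 1.40 ± 0.30 and Jun at 0.80 ± 0.14. Of 21 denervation and neuromuscular junction genes, 8 rose and 0 fell, or 9 adjusted over the list alone (median 0.36, adjusted p = 0.000891, and adjusted p = 0.0449 with an estimated correlation). Runx1, which is induced by denervation, rose by 1.06 ± 0.23, Myod1 by 0.71, Dok7, an activator of the synaptic kinase MuSK, by 0.60 ± 0.11 and the receptor subunit Chrnb1 by 0.52 ± 0.10. Of 12 polyamine genes, 5 fell and 0 rose, or 6 and 2 adjusted over the list alone (median -0.22, adjusted p = 0.000678, and adjusted p = 0.018 with an estimated correlation). Odc1, the first enzyme of polyamine synthesis, fell from 239 to 106 CPM (-1.17 ± 0.14, adjusted p = 1.77e-09) and Amd1 from 1470 to 729 CPM (-1.01 ± 0.16).

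Of 28 genes of fatty acid oxidation, 14 rose and 0 fell at 92 weeks, or 17 adjusted over the list alone (median 0.30, adjusted p = 4.54e-07, and adjusted p = 0.567 with an estimated correlation). Among them were Acadl at 0.49, Hadhb at 0.47 and Acadm at 0.44. Of 15 genes of PGC-1alpha and mitochondrial biogenesis, 5 rose and 0 fell, or 8 and 1 adjusted over the list alone (median 0.22, adjusted p = 0.00623, and adjusted p = 0.216 with an estimated correlation). Examples were Esrrg at 0.83 and Perm1 at 0.59 (11 of 12 animals). Of 23 glycolysis genes, 9 fell and 1 rose, or 12 and 3 adjusted over the list alone (median -0.20, adjusted p = 0.000891, and adjusted p = 0.54 with an estimated correlation). Pgk1 was at -0.37. Of 14 fast fibre genes, 8 fell and 2 rose, or 9 and 2 adjusted over the list alone (median -0.29, adjusted p = 0.000891, and adjusted p = 0.54 with an estimated correlation). Myl1 was at -0.64. Of 12 slow fibre genes, 2 rose and 0 fell by either adjustment (median 0.32, adjusted p = 0.00846, and adjusted p = 0.795 with an estimated correlation), among them myoglobin (Mb) at 1.05 ± 0.26 (11 of 12 animals). The other, Casq2, was at 0.80 (adjusted p = 0.0339) and lost its call without young control replicate 5 or 11, at 0.76 (adjusted p = 0.0554 in both), and with the adipocyte covariate, at 0.57 (adjusted p = 0.107, range over all alternatives 0.00219 to 0.107). The slow myosin Myh7 varied widely within groups, from 1.56 to 930 CPM in the young controls, 0 to 691 CPM at 76 weeks and 8.24 to 1250 CPM at 92 weeks. With the slow fibre covariate, 1853 genes were called at 92 weeks in place of 2212. Whether the share of slow fibres differed between samples for reasons other than age was not tested. Of 34 proteasome subunits, 10 fell and 0 rose by either adjustment (median -0.13, adjusted p = 6.16e-05, and adjusted p = 0.608 with an estimated correlation). Psma3 was at -0.35, and with library totals 4 of the list fell (median -0.07).

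Of 27 extracellular matrix genes, 15 fell and 0 rose at 92 weeks, or 18 adjusted over the list alone (median -0.48, adjusted p = 7.94e-10, and adjusted p = 0.294 with an estimated correlation). They included Col3a1 at -1.20 ± 0.20 and Col1a2 at -1.18, and with library totals 9 of the list fell (median -0.44). Of 10 tenocyte markers, 8 fell and 0 rose by either adjustment (median -1.53, adjusted p = 0.00153, and adjusted p = 0.565 with an estimated correlation). Of 12 markers of fibro-adipogenic progenitors, 3 fell and 0 rose by either adjustment (median -0.15, adjusted p = 0.0478, and adjusted p = 0.795 with an estimated correlation), and 1 of 12 adipocyte markers, leptin (Lep, 2.80 ± 0.64, 11 of 12 animals), rose (median 0.71, adjusted p = 0.0451, and adjusted p = 0.852 with an estimated correlation). With the tenocyte markers as a covariate, the median of the extracellular matrix list was -0.12 with 4 members lower, and Col1a1 moved from -1.15 ± 0.25 to -0.45 (adjusted p = 0.0949, range over all alternatives 1.81e-06 to 0.0949).

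Of the panel, 3 genes rose and 7 fell at 92 weeks. Myh2 (1.20 ± 0.38, adjusted p = 0.0211, at most 0.0863 over the alternatives), Myh1 (0.87 ± 0.22, adjusted p = 0.00278, 11 of 12 animals) and Cdkn1a (0.64 ± 0.23, adjusted p = 0.0421) rose. Igf1 (-1.08 ± 0.18), Mstn (-0.77 ± 0.12), Fkbp5 (-0.64), Fbxo32 (-0.75 ± 0.23, adjusted p = 0.0148, 11 of 12), Myh4 (-0.38 ± 0.10, adjusted p = 0.00318), Col1a1 and Col3a1 fell. Chrna1 (0.36 ± 0.14, adjusted p = 0.0598, 10 of 12 higher) and Trim63 (-0.47, adjusted p = 0.162, range over all alternatives 0.0331 to 0.531, 11 of 12 lower) did not pass. Without young control replicate 11, Fbxo32 was at -0.48 (adjusted p = 0.114, range over all alternatives 0.00321 to 0.114) and Chrna1 at 0.41 (adjusted p = 0.037, range 0.0205 to 0.126). Cdkn1a stayed near its size but lost its call without young control replicate 5 (0.62, adjusted p = 0.0599), without replicate 8 of the animals of 92 weeks (0.63, adjusted p = 0.0551) and with the tenocyte, slow fibre or adipocyte covariate (0.62, 0.62 and 0.61, range over all alternatives 0.000242 to 0.0684).

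Between 76 and 92 weeks, in animals obtained and matched at the same ages per the labels, 5 genes were higher and 0 lower, with 997 at an unadjusted p under 0.05. Gpnmb rose from 2.93 to 23.3 CPM (3.00 ± 0.53, adjusted p = 0.00122, 10 of 12 animals), Otud1, a deubiquitinase, from 11.2 to 28.8 CPM (1.36 ± 0.22, adjusted p = 0.000452, 11 of 12), the immediate early transcription factor Klf4 by 0.81 ± 0.16 (adjusted p = 0.0116, 11 of 12) and Abra, an actin-binding activator of SRF signalling, by 0.69 ± 0.15 (adjusted p = 0.025, 12 of 12). The other was Mmp12, the macrophage elastase (5.68 ± 0.99, adjusted p = 0.00119, 9 of 12), which was chosen after its values were seen. Without replicate 8 of the animals of 92 weeks, Gpnmb was at 1.92 (adjusted p = 0.109, range over all alternatives 4.91e-05 to 0.109), and 4 genes were higher and 1 lower. Gpnmb also lost its call in a fit of only the groups compared (3.00, adjusted p = 0.0649) and with limma voom and quality weights (1.33, adjusted p = 0.0723). Abra lost its call in the fit of only these groups (0.69, adjusted p = 0.0527), without the R libraries (0.66, adjusted p = 0.0797), without the highest and lowest totals (0.66, adjusted p = 0.0942) and with the slow fibre covariate (0.47, adjusted p = 0.505, range over all alternatives 0.000139 to 0.505). Klf4 lost it without the R libraries (0.79, adjusted p = 0.0572) and with the slow fibre covariate (0.74, adjusted p = 0.136, range 0.000971 to 0.136). With limma voom and quality weights in place of edgeR, 564 genes were called.

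Of the 24 lists that camera called between 76 and 92 weeks, 4 held with an estimated correlation. Of 13 immediate early genes, 1 rose over all genes and 5 adjusted over the list alone (median 0.59, adjusted p = 2.21e-11, and adjusted p = 0.00325 with an estimated correlation). Denervation and neuromuscular junction genes had a median of 0.19 (0 of 21 called by either adjustment, adjusted p = 0.0147 with an estimated correlation). Polyamine genes had a median of -0.12 (0 of 12 over all genes, 1 lower adjusted over the list alone, adjusted p = 0.0071 with an estimated correlation). Circadian clock genes had a median of -0.17 (0 of 17 over all genes, 3 higher and 5 lower adjusted over the list alone, adjusted p = 0.0147 with an estimated correlation). Among the lists that lost the call were the slow fibre genes (0 of 12 over all genes and 1 higher adjusted over the list alone, median 0.89, adjusted p = 1.17e-13, and adjusted p = 0.0802 with an estimated correlation), macrophage markers (0 of 15 over all genes and 5 higher adjusted over the list alone, median 0.36, adjusted p = 0.385 with an estimated correlation) and erythroid markers (0 of 6 and 4 likewise, median 1.06, adjusted p = 0.454 with an estimated correlation). The median of the erythroid markers was -0.01 without replicate 8 of the animals of 92 weeks.

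The last question was how far each intervention resembled ageing. Across the 13838 genes, which are not independent replicates, the fold changes of CR and of 92 weeks correlated with Pearson's r = 0.29 (Spearman's rho = 0.20), those of CR plus IR and 92 weeks with r = 0.30 (rho = 0.22), and those of IR and 92 weeks with r = 0.43 (rho = 0.37). For 76 weeks the values were r = 0.24 for CR (rho = 0.19), 0.23 for CR plus IR (rho = 0.20) and 0.42 for IR (rho = 0.37). All of these share the young controls, and simulated data without any group difference gave r = 0.50 to 0.51 from that alone. The SD of r over 200 bootstraps was 0.07 to 0.10. The covariance was above the simulated 0.027 in each case, by 0.043 for CR, 0.018 for IR and 0.052 for CR plus IR at 92 weeks, and by 0.024, 0.012 and 0.026 at 76 weeks. With the young controls divided between the 2 sides, r at 92 weeks was 0.17 and 0.16 for CR, 0.11 and 0.16 for IR and 0.18 in both divisions for CR plus IR.

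Genes called both under CR and at 92 weeks were counted by direction: 340 were higher in both (233.3 by chance), 405 lower in both (195.7), 170 higher under CR and lower at 92 weeks (210) and 201 the reverse (217.4). For CR plus IR, 395 were higher in both (257.8 by chance), 424 lower in both (214.5), 172 higher and then lower (232.1) and 193 the reverse (238.2). At 76 weeks, CR shared 207 higher genes (143.3 by chance) and 223 lower genes (111.7), with 95 higher and then lower (119.8) and 163 the reverse (133.5). CR plus IR shared 228 higher (158.4 by chance) and 235 lower genes (122.4) with the animals of 76 weeks, with 86 higher and then lower (132.5) and 163 the reverse (146.3). For IR, 2 genes were lower in both at 76 weeks and 1 at 92 weeks. The chance numbers make no allowance for the shared controls, so the counts were repeated with the young controls divided. CR and 92 weeks then shared 150 higher (125.5 by chance) and 202 lower genes (106.2), with 258 opposite (231.1), in the first division, and 122 higher (81.5), 151 lower (67.4) and 164 opposite (148.5) in the other. For CR plus IR and 92 weeks these were 190 higher (141.1), 214 lower (116.7) and 253 opposite (256.8), and 146 higher (90), 162 lower (73.8) and 162 opposite (163.3). CR and 76 weeks shared 68 higher (62.8) and 93 lower genes (42.3) with 136 opposite (104.4), and 59 higher (44.3) and 78 lower (38.4) with 112 opposite (82.6). For CR plus IR and 76 weeks there were 84 higher (70.6), 93 lower (46.4) and 138 opposite (115.9), and 64 higher (49), 83 lower (42.1) and 106 opposite (90.8). For IR there were 0. Col3a1, Col1a1, Igf1, Actc1, Amd1, Smox and Myl1 fell both under CR and at 92 weeks, whereas Fkbp5 and Mstn rose under CR and fell at 92 weeks. With the tenocyte covariate, however, Col1a1 lost its call at 92 weeks, while under CR it was at -2.57 ± 0.20.

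**Figure D5:**
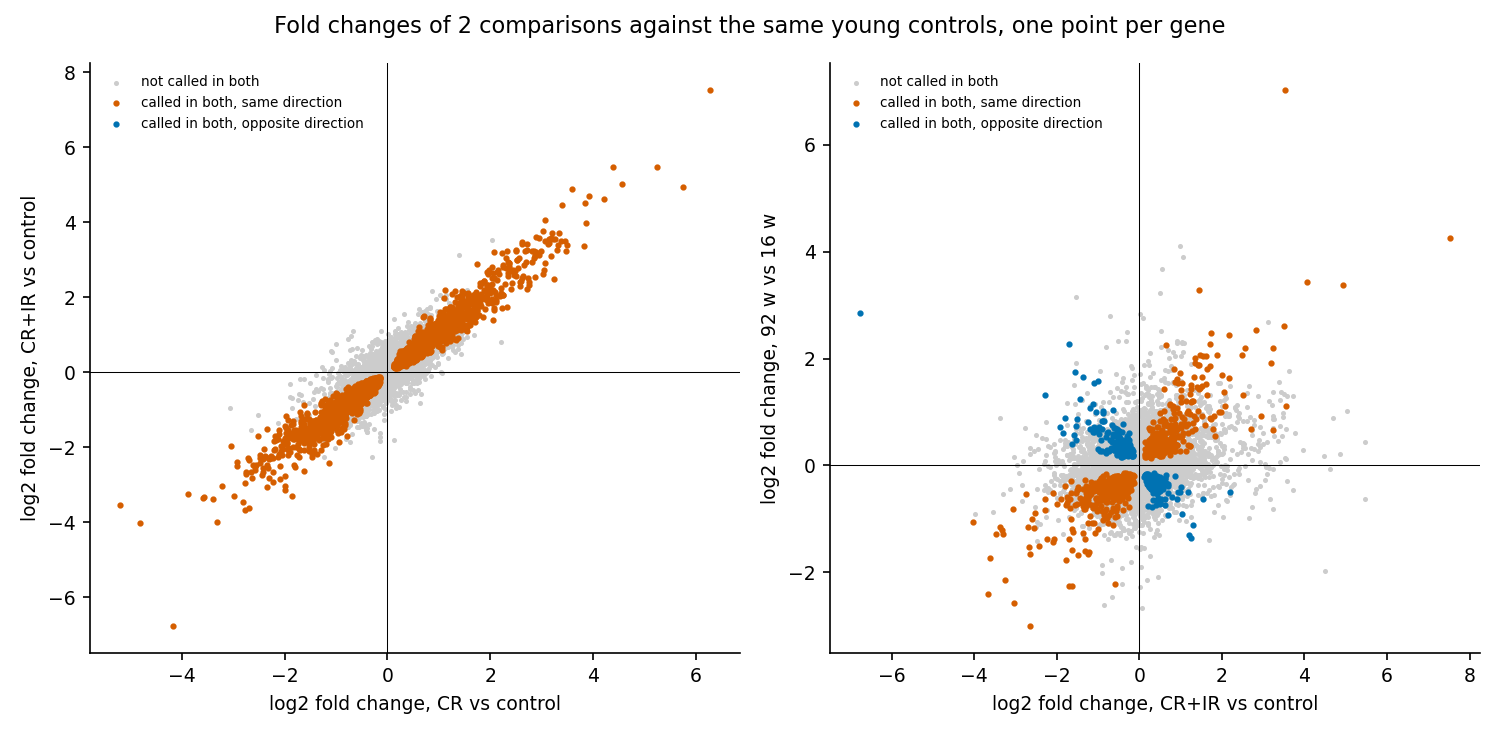
Each point is 1 of 13838 genes, with log2 fold changes against the young controls (n = 12 per group) under CR and CR plus IR on the left, and under CR plus IR and at 92 weeks on the right. The right-hand pair correlates with r = 0.30, or 0.18 with the young controls divided. Shared controls alone gave r = 0.50 in simulated data without group differences, where the covariance was 0.027 against 0.079 in the real data.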

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

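The scaling by library totals, the covariates (the mean level of the tenocyte, adipocyte or slow fibre genes, or the level of Arntl) and the fits without single libraries were chosen after seeing the data, and the others before it. Under these alternatives, 142 counts of called genes stayed within 1.5 times the reported count and 20 did not, and 42 counts of called lists did and 12 did not. Of 8152 values of named genes, 7956 stayed on their side of the threshold, 84 of which, called neither way, changed sign. Another 155 lost a call and 36 gained one in the same direction, and 5 that were called with or without the alternative reversed. DESeq2, the other size factors, a scaling without mitochondrially encoded genes and the R covariate left all 452 named results on their side of the threshold. For IR, DESeq2 called 6 genes, no filter 7, a fit of only the groups compared 7, voom with quality weights 15, the adipocyte covariate 13, and the fits without the R libraries and with the Arntl covariate 1 each. Between CR plus IR and CR, no filter gave 4 genes, and the R covariate and the fit without the R libraries 1 each. The interaction had 72 genes without a filter. Voom with quality weights called 2789 genes at 76 weeks, 3899 at 92 weeks and 564 between them, where DESeq2 called 14, the fit of only these groups 19 and the slow fibre covariate 3. With the Arntl covariate, 3371 genes were called for CR, 3045 for CR plus IR and 3355 for CR plus IR against IR. At 76 weeks 936 were called with it, 764 of them among the 1313 called without it, and at 92 weeks 2123. The cause was not tested.

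With an estimated correlation, camera called 2 lists for CR, 1 for IR, 3 at 92 weeks, 4 between 76 and 92 weeks, and 0 for CR plus IR against control, CR or IR, for the interaction and at 76 weeks. Fry, which does not compare a list with the other genes, called 22 lists for CR, 22 for CR plus IR against control and 20 against IR. It called 1 for IR, 6 at 76 weeks, 12 at 92 weeks and 4 between them. For CR plus IR against CR and for the interaction it called 0. Against IR, 10 lists were called without CR plus IR replicate 4 and 17 without replicate 9. Without young control replicate 5, 5 lists were called at 76 weeks, and 5 without replicate 11. With divided young controls, where fewer samples remain and the shared error is gone, r with 76 weeks was 0.11 and 0.09 for CR, 0.07 and 0.11 for IR, and 0.11 and 0.10 for CR plus IR. With 92 weeks it was 0.17 and 0.16, 0.11 and 0.16, and 0.18 and 0.18. The reversed values were Comp at 0.12 and Angptl7 at 0.23 at 92 weeks with the tenocyte covariate, Myh7 at -0.51 under CR and -0.58 at 92 weeks with the slow fibre covariate (a list that holds it), and Pdk4 at -0.01 under CR plus IR with the Arntl covariate. The cause was not tested for these values either. In simulated data, 63.5% of 1.5-fold changes were recovered under CR and 71% at 92 weeks, so smaller changes are often not detectable at this depth and number of animals.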

Other observations

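The genes of the first paragraphs outside the panel were chosen after their values were seen, as were the tests of the markers that are not matrix proteins, of Dbp, of the denervation list and of small changes after immobilization, and the covariate fits. The circadian clock list was not called by camera under CR (8 of 17 higher and 3 lower over all genes and adjusted over the list alone, adjusted p = 0.113). Its members moved both ways. Fry, which tests for a shift of the list in 1 direction, gave an adjusted p of 8.37e-09. Arntl, the activator of the clock, fell from 47.8 to 15.4 CPM (-1.63 ± 0.17, adjusted p = 6.34e-13) and its relative Npas2 changed by -2.19 ± 0.39. The repressor genes Per1 (2.66 ± 0.24), Per2 (1.51 ± 0.28) and Ciart (2.20 ± 0.32) rose. All of these moved in 12 of 12 CR animals. Under CR plus IR, Arntl changed by -1.89 ± 0.17 and Per1 by 2.87 ± 0.24. At 76 weeks Arntl was lower too (-0.67 ± 0.16, adjusted p = 0.00417), and Per2 (1.10 ± 0.28) and Dbp (0.83 ± 0.22) were higher. At 92 weeks Arntl did not pass (-0.18 ± 0.16, adjusted p = 0.502).

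Of 6 erythroid markers, 4 rose and 1 fell under CR (median 1.29, camera adjusted p = 0.412), with Hba-a1 from 37.1 to 115 CPM (1.63 ± 0.43, adjusted p = 0.00157) and the first enzyme of haem synthesis, Alas2, at 1.38 ± 0.50. At 92 weeks 4 rose and 0 fell (median 1.90, adjusted p = 0.129), with Hba-a1 at 2.04 ± 0.44 (11 of 12 animals). The highest animal was replicate 8, with 985 CPM of Hba-a1, and without it the median of the erythroid markers was 0.67 and 1 rose. The nicotinic receptor gene Chrna9 rose under CR from 0.05 to 1.39 CPM (4.56 ± 0.66, adjusted p = 2.86e-08, 12 of 12 animals), while Myod1 fell by 1.53 ± 0.17 (adjusted p = 3.84e-12, 12 of 12) under CR and rose at 92 weeks. At 76 weeks the leptin gene Lep was higher (2.15 ± 0.64, adjusted p = 0.0194, 10 of 12), as at 92 weeks.

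The fall of extracellular matrix genes under CR came with a fall of tenocyte and progenitor markers, which raises the question whether tissue or cells were lost in place of transcripts. With the tenocyte covariate the median was -0.99 (quartiles -1.40 to -0.49) against -1.29 without it, and 22 of 27 genes fell. Col1a1 was at -2.57 ± 0.20 and Col3a1 at -3.02 ± 0.19 in that fit. The fall was thus larger than the slope on the tenocyte markers within groups accounts for. This does not decide on tendon carried into the control samples, because the tenocyte markers differ with the diet themselves and some are matrix proteins. A general loss of fibroblast-lineage cells predicts a fall of the 6 progenitor markers that are not matrix proteins. Their median was -0.27 (SE of the mean 0.27, from -1.66 to 0.20), above -0.64, the bound set for this test from the matrix change. This does not decide, because the markers were few and spread widely, and the SE belongs to their mean and not to their median. Pdgfra was at 0.02 (adjusted p = 0.942), Ly6a at -0.27 (adjusted p = 0.0842) and Cygb at 0.20, while Pi16 was at -1.66 and Cd34 at -0.57. Open are tendon carried into the control samples, a general loss of these cells, a loss of the subset that carries Pi16 and a lower transcription of matrix genes under CR. These may act together, and the loss of the subset and the lower transcription were not tested.

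The clock genes and the rest of the CR difference moved together, and restricted animals may have differed in the time of feeding or of death, which the labels do not give. With the Arntl covariate, 50% of the genes called for CR (2676 of 5357) were called in the same direction, which does not decide, because Arntl differs with the diet itself. Another phase along the clock of the other animals predicts a higher Dbp. Within groups Dbp fell with Arntl (slope -0.48, r = -0.38), which gives 0.79 for CR. The measured value was 0.59 (95% interval 0.16 to 1.02). For CR plus IR the slope gives 0.92 against the controls, where Dbp was at 0.38 (-0.04 to 0.81, adjusted p = 0.15), and 0.69 against IR, where it was at -0.28 (-0.71 to 0.14, adjusted p = 0.311). The IR group itself had 34.6 CPM of Arntl and 95.5 CPM of Dbp, against 47.8 and 60.1 CPM in the young controls. A slope within groups does not decide a difference between groups, so a shift in phase stays open, and the time of sampling, the time of meals and the lower intake cannot be told apart, since each is confounded with CR.

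Immobilization was followed by few called genes. Too few animals or reads are argued against for changes of 1.5-fold, of which 65% were recovered in simulated data for the same comparison, but stay open for smaller ones, since 30.5% of the genes with the smallest simulated change were. That the muscle came from the leg that was not fixed is consistent with the label of the left quadriceps, with a median of 0.043 for the denervation list and with 0 of 18 panel genes called. A small effect of this form of immobilization on the fixed leg would look alike, so both stay open, and no sample of the other leg was analysed here.

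The 12 animals of each group were also regrouped at random, in 50 splits per comparison including the real one, with the same tests. For the number of called genes, no other split reached the real count for CR (5357 genes, at most 3107 in another split, 1 split as large). The same held for CR plus IR (5897 against 868, 1 split) and CR plus IR against IR (5324 against 1172, 1 split). It also held for 76 weeks (1313 against 25, 1 split) and 92 weeks (2212 against 23, 1 split). These counts argue against chance but do not exclude it. A share of 1 in 50 is the smallest possible here, and it was not corrected for the number of comparisons. For IR (3 against 26, 2 splits) and 92 against 76 weeks (5 against 10, 2 splits) chance stays open, since another split called more genes than the real one. For CR plus IR against CR (0 genes, at most 387 in another split) and the interaction (0, at most 568) the splits decide nothing, since each of the 50 gives at least 0. Single splits called 26 genes for IR and 387 for CR plus IR against CR, where the real ones called 3 and 0. In the split with 387 genes, 7 of the 12 libraries in its first group carried the letter R, against 3 in the real CR plus IR group. In the split with 26 genes there were 2, against 4 in the real IR group. Whether the samples hold a structure beyond their groups, with or without the letter R, was not tested. The split that called 568 genes for the interaction does not decide this. Regrouping there can mix restricted and freely fed animals unevenly, and CR against control alone gave 5357 genes.

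For the number of called lists, 92 against 76 weeks gave 24, with at most 23 in another split and 1 split as large. This does not decide, because the real count was barely above that of another split. A share of 1 in 50 is also the smallest the splits can give, and it was not corrected for the number of comparisons. For this comparison chance therefore stays open. It cannot be excluded for CR (17 lists, at most 17, 3 splits), IR (14 against 17, 4 splits), CR plus IR (15 against 18, 10 splits), CR plus IR against CR (4 against 18, 44 splits), CR plus IR against IR (10 against 19, 22 splits), the interaction (6 against 19, 42 splits), 76 weeks (3 against 19, 46 splits) and 92 weeks (13 against 20, 15 splits). The median of the other splits was 8 to 13 lists.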
